A study of Mus musculus with 8 samples.

How the data were processed

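ChIP-seq was measured in Beta-TC6 cells harvested at confluence, fixed with a protein crosslinker (DSG) and formaldehyde and sonicated, per the labels' protocols. There was 1 library for each of 6 targets (BMAL1, CLOCK, PDX1, H3K4me2, H3K27ac, H2A.Z), each with its deposited peak list, and 2 input libraries whose own reads were not used here. Reads were aligned with Bowtie 1.1.1 to mm10 and processed with HOMER, per the submitters' processing notes; the HOMER version is not given in the sources used here. Peaks were called separately for each library by HOMER findPeaks, per the file headers, in the factor style with a fixed width for BMAL1 (330 bp), CLOCK (204 bp) and PDX1 (234 bp), and in the histone style with variable widths for H3K4me2 (median 939 bp), H3K27ac (median 1163 bp) and H2A.Z (median 500 bp). A factor peak needed at least 13 tags, 4 times the input, 4 times the surrounding 10 kb, a Poisson p-value of 1e-04 and an FDR of 0.001, per the file headers. Histone intervals needed 4 times the input and a Poisson p-value of 0.001, per the file headers. BMAL1, CLOCK and H2A.Z were called against 1 pooled input and PDX1, H3K4me2 and H3K27ac against the other, per the file headers. For H2A.Z the sample description names the other input, while the title of the input sample and the header of the list name the same input as for BMAL1 and CLOCK; the header was followed.

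The deposited normalized tag counts are a signal scaled by HOMER to 10000000 tags per library, per the file headers, and served here for the quintiles of H3K27ac intervals. The authors' score of each peak was used to rank, filter or class peaks within its own list. Shares of BMAL1 and CLOCK peaks in the same score classes were also set side by side, without a test. The deposited fold over input, a ratio made by HOMER, was used for the filter at 8 times the input. The deposited tag counts per interval and the deposited input tags gave the input density per chromosome. Further deposited columns, among them the focus ratio (a fraction), the region size in bp and the p-value of each peak against input and surroundings, were read to check the files and entered no test.

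Total tags per library were 12892080 (BMAL1), 17898856 (CLOCK), 19568242 (PDX1), 26678241 (H3K4me2), 13430083 (H3K27ac) and 18513695 (H2A.Z), per the file headers. A site with fewer tags than the threshold does not enter a list, so the absence of a peak means that none was detectable at this depth. Tag numbers and the share of tags in peaks differed between targets, and scores or ranks were not tested between lists. Wilson 95% intervals on shares cover counting error only.

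Peaks overlapped when they shared at least 1 bp. Overlaps were set against 1000 seeded shuffles of the intervals within their chromosomes (one-sided), and locations against 200 (two-sided). Shares of peaks were compared by two-sided Fisher exact tests, with odds ratios and 95% intervals by the Woolf method and Benjamini-Hochberg adjustment within each family of 28 tests. Candidate enhancers were H3K27ac intervals that overlapped H3K4me2 and lay more than 1 kb from gene ends, and Mantel-Haenszel odds ratios were computed over 5 quintiles of their normalized tag count. Gene positions came from an NCBI RefSeq gene table for GRCm38.p6, which shares the coordinates of mm10. The table gives the span of each gene without strand or exons, so both ends of the 21887 protein-coding genes took the place of transcription start sites, and exons, introns and UTRs were not determined. A gene had a peak when one of its ends was the nearest gene end to the peak centre, within 50 kb. The 15 gene lists held 408 genes, of which 407 matched a protein-coding gene, and were tested with Fisher exact tests against all other protein-coding genes for BMAL1, CLOCK, PDX1 and H3K27ac, adjusted over 60 tests. Genes, peaks and intervals are not replicates. Chromosome densities were related by Pearson and Spearman correlation over chromosomes 1 to 19 and X with 100000 permutations, adjusted over 24 relations. Input density was the number of input tags per kb of H3K4me2 interval, and the density of the second input in H2A.Z intervals correlated with it across chromosomes (r = 0.884).

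The overlap and list tests were tested on simulated data first. All 200 planted overlaps among 1378 simulated CLOCK peaks were recovered with 0 calls differing from a direct search. Simulated lists of 24 genes with 12 planted members were called in 100% of runs, against 0.571% of lists without planted members. These 2 rates describe the simulated lists only and cannot be carried over to the 60 tests of the measured lists. In the measured data the number of lists called for PDX1 went from 6 to 2 against random lists matched on gene territory. Power for smaller hits, such as 5 of 26 genes, was not estimated. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

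Lists, tests, the rule for named genes and most of the settings compared were fixed before the data were examined. The rule named every core clock gene, the genes nearest to the 10 highest BMAL1, 10 highest CLOCK and 5 highest PDX1 peaks, up to 4 genes per beta-cell list with the highest BMAL1 peak on PDX1, and up to 4 members with the highest score of any other list past the threshold. In the beta-cell lists the genes named for a BMAL1, CLOCK or PDX1 peak without such an overlap, P4hb, Car11, and the non-clock genes with shared BMAL1 and CLOCK peaks or with CLOCK on PDX1 were chosen after their values were seen. Some genes that the rule names are not reported here. The alternatives were a stricter overlap (at least 50% of the shorter interval, or centres within 200 bp), the upper 50% of every list by score, H3K4me2 intervals as the background, other windows around gene ends (3 kb, 5 kb, 10 kb), all annotated genes, genes with H3K27ac at a gene end, random lists matched on the territory nearest to each gene (10000 lists) and peaks of at least 8 times the input. Use of gene ends, the score classes, BMAL1 and CLOCK scores of 20 or more, the strata of width and chromosome and the split by input density were added after seeing the data. The 16 planned motifs were not analysed here, since no genome sequence was used.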

Results

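Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in Beta-TC6, a mouse insulinoma line used as a model of the insulin-secreting pancreatic beta cell. The 6 targets were BMAL1 and CLOCK, the partner transcription factors that drive the circadian clock, PDX1, a homeodomain factor central to beta-cell identity, the histone marks H3K4me2 and H3K27ac, which lie at promoters and enhancers, and the histone variant H2A.Z. Each target had 1 library, and 2 input libraries served as controls for peak calling, so the data held no replicates and the tests compared these libraries by the positions of their peaks. Library depth ranged from 12892080 tags for BMAL1 to 26678241 tags for H3K4me2. CLOCK had 17898856 tags, PDX1 19568242, H3K27ac 13430083 and H2A.Z 18513695. The deposited lists held 4125 BMAL1 peaks, 1378 CLOCK peaks, 34883 PDX1 peaks, 41140 H3K4me2 intervals, 29735 H3K27ac intervals and 26455 H2A.Z intervals. Peaks held 0.48% of the BMAL1 tags and 0.16% of the CLOCK tags, against 4.32% for PDX1, 21.0% for H3K4me2, 37.2% for H3K27ac and 3.12% for H2A.Z. Scores are the values of the authors' peak caller, and in the BMAL1, CLOCK and PDX1 lists they are close to the number of tags at a peak. Each score was used within its list, except that H3K27ac and gene-end shares of BMAL1 and CLOCK peaks were set side by side by score class without a test. In the BMAL1 list 2809 peaks (68.1%) had a score of 13 or 14, next to the calling threshold of 13 tags, as did 600 CLOCK peaks (43.5%) and 6836 PDX1 peaks (19.6%).

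The genes of the circadian clock carried the strongest BMAL1 and CLOCK peaks. The highest-scoring BMAL1 peak lay inside Nr1d2, which encodes a nuclear receptor that represses clock genes. It was at chromosome 14, 18238526 to 18238856 (mm10), its centre 415 bp from a gene end, with a score of 408 for BMAL1 and 433 for CLOCK. It was followed by a peak at Tef, a PAR bZIP factor (chromosome 15, 81810955 to 81811285, inside the gene, BMAL1 284, CLOCK 294). The next was at the period gene Per2 (chromosome 1, 91459217 to 91459547, BMAL1 221, CLOCK 249). The Per2 peak spanned the gene end, with its centre 31 bp outside the gene. The rest of the 10 highest BMAL1 peaks were nearest to Nr1d1 (179), Per1 (179), Sphk2 (176), Ciart (174), Cry1 (165), Per3 (152) and Hlf (147). The 10 highest CLOCK peaks were nearest to the same 10 genes, with scores from 151 at Hlf to 433 at Nr1d2. All 10 of these BMAL1 peaks overlapped a CLOCK peak, 8 overlapped H3K4me2, 8 overlapped H3K27ac and 0 overlapped PDX1. The peak assigned to Sphk2, at chromosome 7, 45707539 to 45707869, lies within the span of Dbp (45705100 to 45710203), which encodes another PAR bZIP factor.

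Of the 24 genes on the core clock list, 16 had a BMAL1 peak (66.7%, against 8.84% of the other protein-coding genes) and 17 had a CLOCK peak (70.8% against 4.40%), counting a peak for the gene whose end was nearest within 50 kb. Both proteins were found at 15 genes, and at each of these 15 genes at least 1 BMAL1 peak overlapped CLOCK. Beyond the genes above, they included Arntl, which encodes BMAL1 itself (best score 53 for BMAL1 and 19 for CLOCK), Cry2 (48 and 70), Bhlhe41 (89 and 109), Bhlhe40 (36 and 41) and Nfil3 (21 and 32). Clock had BMAL1 peaks, the best with a score of 30, and no CLOCK peak, whereas Dbp (CLOCK score 140) and Usp2 (CLOCK score 16) had a CLOCK peak only. For Dbp this follows from the assignment, since a BMAL1 peak with a score of 143 at chromosome 7, 45704693 to 45705023, overlapped that CLOCK peak but lay nearer to the end of Car11. Genes with neither included Npas2, Rora, Rorb and the casein kinase genes Csnk1d and Csnk1e. The enrichment of the list gave an odds ratio of 20.6 for BMAL1 (95% CI 8.81 to 48.2, Fisher exact test adjusted p = 1.63e-10) and of 52.8 for CLOCK (21.8 to 128, adjusted p = 1.55e-16). PDX1 peaks were found at 9 of the 24 genes (37.5% against 33.4%, adjusted Fisher p = 0.837).

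BMAL1 and CLOCK bind DNA as a heterodimer, so the overlap of their peaks was examined next. CLOCK peaks overlapped with BMAL1 peaks in 18.7% of cases (258/1378, Wilson 95% CI 16.8 to 20.9), against a mean of 0.104% for shuffled positions within the same chromosomes (one-sided position permutation p = 0.000999, the smallest that 1000 shuffles can give). In the other direction 6.25% of BMAL1 peaks (258/4125, 5.56 to 7.03) overlapped CLOCK. The share rose with the peak score. Of the 116 BMAL1 peaks with scores of 30 or more 76.7% overlapped CLOCK, of the 122 with scores of 20 to 29 41.0%, of the 1078 with scores of 15 to 19 7.88%, and of the 2809 with scores of 13 or 14 1.21% (odds ratio of highest against lowest class 269, 95% CI 156 to 465, adjusted Fisher p = 1.99e-114 over 28 tests). For CLOCK peaks the overlap with BMAL1 went from 4.33% of those with scores of 13 or 14 to 74.6% of the 138 with scores of 30 or more. High-scoring CLOCK peaks in BMAL1 peaks outside the core clock list, chosen after their values were seen, included those inside Adh5, an alcohol dehydrogenase gene (109), Mcf2l (91) and Hif1a, the hypoxia-inducible factor gene (88), and those next to Klf11 (89) and Dgat2, a triglyceride synthesis gene (76).

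**Figure D1:**
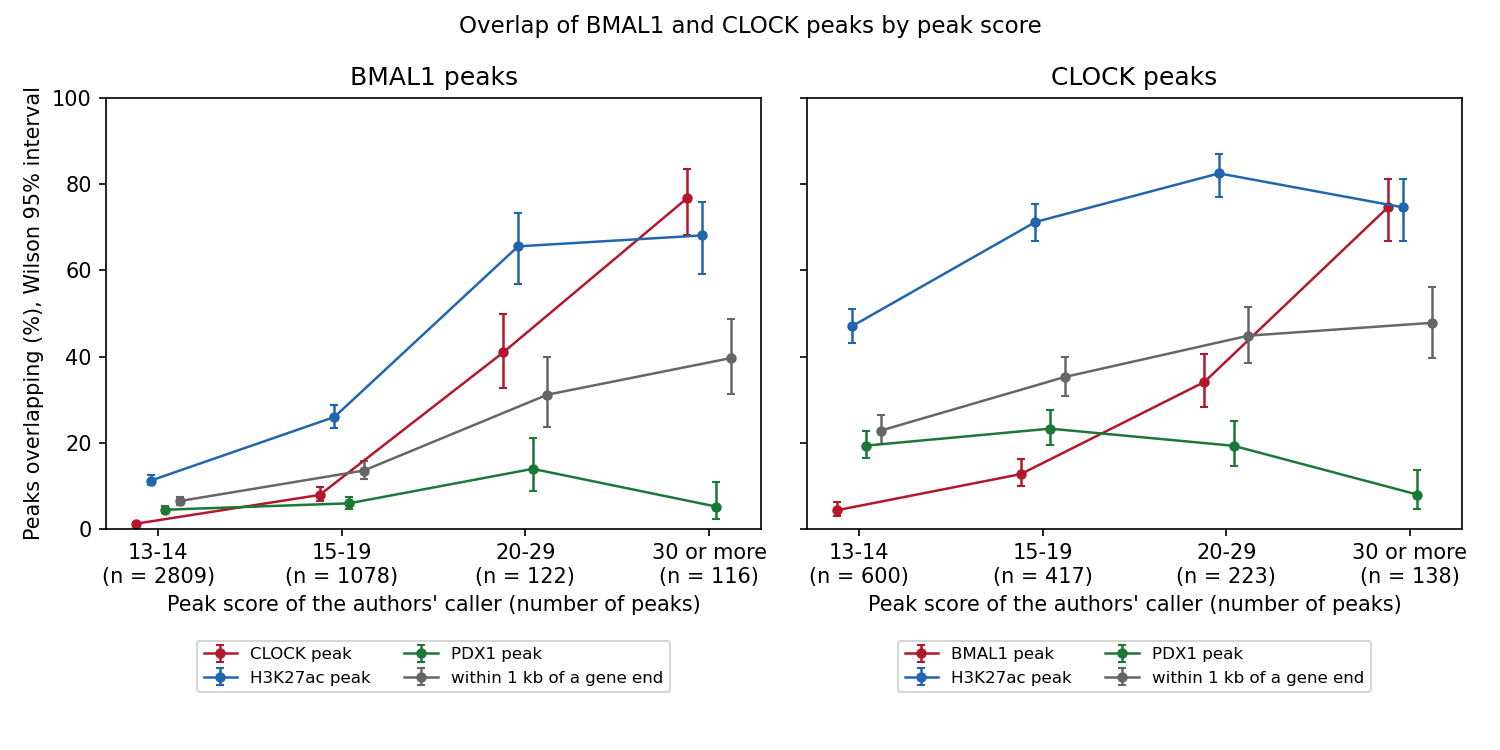
Share of BMAL1 peaks (left) and CLOCK peaks (right) that overlap the other clock factor, H3K27ac or PDX1, or lie within 1 kb of a gene end (y axis, percent, bars are Wilson 95% intervals), by class of the peak score (x axis, with the number of peaks). Overlap between the factors goes from 1.21% to 76.7% of BMAL1 peaks and from 4.33% to 74.6% of CLOCK peaks, while 7.97% of the highest CLOCK class overlap PDX1.

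The lists differed in where they lay relative to genes. CLOCK peaks were within 1 kb of the end of a protein-coding gene in 32.7% of cases (450/1378, 95% CI 30.2 to 35.2), BMAL1 peaks in 9.99% (412/4125, 9.11 to 10.9) and PDX1 peaks in 2.13% (742/34883, 1.98 to 2.28). Shuffled positions gave means of 3.11%, 2.93% and 2.94%, so that CLOCK and BMAL1 lay above and PDX1 below the range of 200 shuffles (two-sided position permutation p = 0.00995 for each, the smallest that 200 shuffles can give). PDX1 peaks were inside the span of a protein-coding gene in 44.8% of cases, BMAL1 peaks in 50.8% and CLOCK peaks in 54.6%. They were both outside genes and more than 1 kb from gene ends in 54.0%, 45.2% and 30.7%. The share at gene ends was 23.5% for H3K4me2, 23.0% for H3K27ac and 23.5% for H2A.Z. Because the gene table used here has no strand, a gene end stands for either the start or the end of transcription.

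CLOCK peaks lay mainly in acetylated chromatin, and most BMAL1 and PDX1 peaks did not. H3K27ac overlapped 62.8% of CLOCK peaks (866/1378, 60.3 to 65.4), 18.3% of BMAL1 peaks (754/4125, 17.1 to 19.5) and 21.1% of PDX1 peaks (7367/34883, 20.7 to 21.6). H3K4me2 overlapped 55.4%, 18.4% and 23.6% of the same lists, and H2A.Z overlapped 19.4%, 8.63% and 3.12%. Each of these 9 shares exceeded all 1000 shuffles, whose means ranged from 0.973% to 2.69%. The odds of H3K27ac overlap were 7.56 times higher for CLOCK peaks than for BMAL1 peaks (95% CI 6.61 to 8.65, Fisher exact test adjusted p = 1.04e-202 over 28 tests). This gap was smaller among high-scoring peaks, with H3K27ac at 11.2% of BMAL1 and 47.0% of CLOCK peaks at scores of 13 or 14, 26.0% and 71.2% at 15 to 19, and 65.6% and 82.5% at 20 to 29. The shares were 68.1% and 74.6% at 30 or more. Gene-end shares in the highest class were 39.7% and 47.8%. Score classes of the 2 libraries differ in depth, and the gap was not tested within them. BMAL1 peaks that overlapped CLOCK were in H3K27ac in 80.2% of cases (207/258), against 14.1% of the BMAL1 peaks outside CLOCK (547/3867, odds ratio 24.6, adjusted Fisher p = 4.25e-113). These shared sites overlapped H3K4me2 in 69.4% of cases and H2A.Z in 27.1%, and 45.0% of them were within 1 kb of a gene end. Among PDX1 peaks the share in H3K27ac went from 7.52% at scores of 13 or 14 to 41.1% at scores of 30 or more.

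The series concerns enhancers of the beta cell, and PDX1 was the beta-cell factor profiled beside the clock factors. PDX1 peaks overlapped 19.4% of CLOCK peaks (267/1378, 95% CI 17.4 to 21.5), 5.14% of BMAL1 peaks (212/4125, 4.51 to 5.86) and 11.2% of the BMAL1 peaks on CLOCK (29/258, 7.94 to 15.7). The shuffled means were 0.637%, 0.867% and 0.780% (one-sided position permutation p = 0.000999 for each). A second test took the 41140 H3K4me2 intervals and counted factors that had peaks anywhere in the same interval. Its odds ratios are not on the scale of the peak overlaps above. Intervals with PDX1 held CLOCK in 2.85% and BMAL1 in 2.53% of cases, against 1.59% and 1.66% of those without. The odds ratios were 1.82 (95% CI 1.55 to 2.13) and 1.54 (1.31 to 1.81). They were much smaller than the 23.4 (19.5 to 28.2) that the same test gave for CLOCK in intervals with BMAL1 against those without. The clock sites that carried PDX1 were mostly away from gene ends, as were PDX1 peaks in general. Within 1 kb of a gene end lay 2.13% of all PDX1 peaks, 8 of the 267 CLOCK peaks on PDX1 and 8 of the 212 BMAL1 peaks on PDX1. The contrasts that follow therefore largely restate where PDX1 peaks lie. Among CLOCK peaks more than 1 kb from a gene end 27.9% overlapped PDX1 (259/928), against 1.78% of those within 1 kb (8/450, odds ratio 21.4, 95% CI 10.5 to 43.7, adjusted Fisher p = 3.2e-39). The corresponding shares of BMAL1 peaks were 5.49% (204/3713) and 1.94% (8/412), with an odds ratio of 2.94 (1.44 to 5.99, adjusted Fisher p = 0.000962). BMAL1 peaks on PDX1 were in H3K27ac in 49.5% of cases, against 16.6% of the BMAL1 peaks outside PDX1 (odds ratio 4.94, adjusted Fisher p = 2.22e-26), and CLOCK peaks on PDX1 in 76.0% against 59.7% (odds ratio 2.14, adjusted p = 6.11e-07). H2A.Z went the other way at CLOCK peaks, with 9.74% on PDX1 and 21.7% outside (odds ratio 0.389, adjusted Fisher p = 4.9e-06), and for BMAL1 the shares of 5.66% and 8.79% did not differ past the threshold (adjusted p = 0.136). These contrasts of marks were not split by distance to gene ends, and 23.5% of H2A.Z intervals lay within 1 kb of a gene end.

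The highest-scoring CLOCK peaks in PDX1 peaks, named after their values were seen, were inside Mcf2l (chromosome 8, 12934724 to 12934928, score 91) and Mknk1 (chromosome 4, 115850696 to 115850900, score 65), and both also overlapped BMAL1 and H3K27ac. Those inside Trerf1 (39) and Myt1, a zinc-finger gene of endocrine cells (26), overlapped H3K4me2 and H3K27ac and not BMAL1. The 5 highest PDX1 peaks were nearest to Gm3415 (761), Bicc1 (527), Med13l (395), 1700123K08Rik (390) and Gm5565 (376). Only the peak near Med13l, 297096 bp from the gene, was in H3K4me2 or H3K27ac, and 3 of the other peaks lay on chromosome 5.

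Co-occupancy was then tested among candidate enhancers, defined as the 12236 H3K27ac intervals that overlapped H3K4me2 and lay more than 1 kb from gene ends. PDX1 was present in 4805 of them (39.3%), CLOCK in 360 and BMAL1 in 311, and 33 held all 3 factors. BMAL1 occupied 3.43% of the enhancers with PDX1 (165/4805) and 1.96% of those without (146/7431), an odds ratio of 1.77 (95% CI 1.42 to 2.22, Fisher exact test p = 6.8e-07). CLOCK occupied 4.18% (201/4805) and 2.14% (159/7431), an odds ratio of 2.00 (1.62 to 2.47, Fisher exact test p = 1.44e-10). All 3 factors were more frequent in intervals with more H3K27ac tags: from the lowest to the highest quintile of H3K27ac tags, PDX1 went from 23.0% to 55.1%, CLOCK from 0.466% to 7.30% and BMAL1 from 0.660% to 5.29%. Within these quintiles the odds ratios were 1.36 for BMAL1 (Mantel-Haenszel, 95% CI 1.08 to 1.71) and 1.41 for CLOCK (1.14 to 1.75). H3K27ac intervals were 500 to 35416 bp wide, and the trend with tags was not separated from width. Within quintiles of width, strata added after seeing the data, the odds ratios were 1.34 for BMAL1 (1.06 to 1.69) and 1.40 for CLOCK (1.13 to 1.74). With only the upper 50% of every list by score, the CLOCK odds ratio was 1.48 (1.00 to 2.17) and no longer passed the threshold (Fisher exact test p = 0.0512). Intervals are not replicates, and the p-values describe these libraries alone.

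Genes of insulin secretion were then examined through lists fixed in advance. Among 52 genes of vesicle exocytosis, the machinery that docks and fuses insulin granules, 12 had a BMAL1 peak (23.1% against 8.87% of other genes, odds ratio 3.08, 95% CI 1.61 to 5.88, adjusted Fisher p = 0.0054 over 60 tests). These included Rph3al (score 21) and Rab3a (19), both of the RAB3 pathway of granule docking, and the active-zone gene Pclo (15). In 9 of the 12 genes the best BMAL1 peak had a score of 13 or 14, and 0 of the 12 had a BMAL1 peak on CLOCK. The calcium sensor gene Syt1 was the only exocytosis gene whose BMAL1 peak overlapped PDX1 (chromosome 10, 108485925 to 108486255, score 13, in H3K4me2 and H3K27ac). CLOCK peaks were found at 5 of the 52 genes (adjusted Fisher p = 0.164), with the best scores at Rab37 (23) and Unc13a (19). The BMAL1 call ended with the upper 50% of every list by score (adjusted Fisher p = 0.334), within 10 kb of the gene ends (adjusted Fisher p = 0.125) and among genes with H3K27ac at a gene end (adjusted Fisher p = 0.214). It also ended against random lists matched on the territory of their genes (adjusted permutation p = 0.141), and with BMAL1 and CLOCK scores of 20 or more only 1 of the 52 genes was left (adjusted Fisher p = 0.638).

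Among 46 genes at diabetes loci 13 had a BMAL1 peak (28.3% against 8.86%, odds ratio 4.05, 95% CI 2.13 to 7.71, adjusted Fisher p = 0.000715). The highest score, 120, belonged to Abcc8, the sulfonylurea receptor subunit of the beta-cell potassium channel, at chromosome 7, 46141828 to 46142158, inside the gene and in H3K27ac but outside CLOCK and PDX1 peaks. Jazf1 (21) and Dgkb (17) came next, and Slc30a8, the granule zinc transporter, had a BMAL1 peak with a score of 15 at chromosome 15, 52316152 to 52316482, on a PDX1 peak with a score of 165. The other BMAL1 peak on PDX1 at these loci was near C2cd4b (13). In 8 of the 13 genes the best score was 13 or 14, and the call ended against territory-matched lists (adjusted permutation p = 0.0720) and within 10 kb of the gene ends (adjusted Fisher p = 0.700). It also ended among genes with H3K27ac at a gene end (odds ratio 3.38, adjusted Fisher p = 0.0552) and at BMAL1 scores of 20 or more (2 genes, odds ratio 5.50, adjusted Fisher p = 0.133). With the upper 50% of every list by score it passed (7 genes, odds ratio 3.37, adjusted Fisher p = 0.0270). CLOCK peaks were at 4 of the 46 genes (adjusted Fisher p = 0.280), among them Kcnj11 (16), which encodes the pore of the same channel, and Abcc8 (13). The centre of the CLOCK peak at Abcc8 lay 68 bp outside the gene.

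The insulin processing and granule list had CLOCK peaks at 5 of 26 genes (19.2% against 4.46%, odds ratio 5.11, 95% CI 1.92 to 13.6, adjusted Fisher p = 0.016). They were the amylin gene Iapp (19), Vgf (18), the granin genes Chga (16) and Scg2 (15), and P4hb (15). With the upper 50% of every list by score 5 of 26 genes had a CLOCK peak (odds ratio 9.35, adjusted Fisher p = 0.00247). None of these peaks reached a score of 20, and the call ended in the territory-matched test (adjusted permutation p = 0.0720), within 10 kb of gene ends (adjusted Fisher p = 0.125) and among genes with H3K27ac at a gene end (adjusted Fisher p = 0.234). BMAL1 peaks were at 4 of the 26 genes (adjusted Fisher p = 0.461), and those of Slc30a8 (15) and Ptprn2 (14) were on PDX1. The list of stimulus-secretion coupling, from glucose sensing to calcium entry, had BMAL1 peaks at 10 of 53 genes (18.9%, adjusted Fisher p = 0.0609) and CLOCK peaks at 5 (adjusted p = 0.169). The beta-cell transcription factor list had BMAL1 peaks at 6 of 26 genes (23.1%, adjusted Fisher p = 0.0609), the best at Tox3 (19) and Rfx6 (17), and a CLOCK peak at 1 gene, Myt1 (adjusted p = 1). With the upper 50% of every list by score the transcription factor list passed for BMAL1 (5 of 26 genes, odds ratio 4.46, adjusted Fisher p = 0.0286), and in the other settings its adjusted p ranged from 0.510 to 1. The list had 0 of 26 genes within 10 kb of gene ends and 0 of 26 at scores of 20 or more. In these last 2 lists 0 genes had a BMAL1 peak on PDX1.

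PDX1 peaks were more frequent at 6 of the gene lists than at other genes, and 2 of these calls held against territory-matched lists. They were found at 19 of 26 insulin processing and granule genes (73.1% against 33.4%, odds ratio 5.41, adjusted Fisher p = 0.0004), led by Chga (192), Slc30a8 (165), Cpe (155) and Iapp (94). They were also found at 18 of 26 beta-cell transcription factor genes (odds ratio 4.49, adjusted Fisher p = 0.00101), among them Tox3 (198), Nkx2-2 (160) and Nkx6-1 (94). Diabetes loci had PDX1 peaks at 32 of 46 genes (odds ratio 4.56, adjusted Fisher p = 7.65e-06), stimulus-secretion coupling at 32 of 53 (odds ratio 3.04, adjusted p = 0.0004), vesicle exocytosis at 30 of 52 (odds ratio 2.72, adjusted p = 0.00138) and markers of other islet endocrine cells at 10 of 13 (odds ratio 6.64, adjusted p = 0.0054). Against territory-matched lists the granule genes (adjusted permutation p = 0.0175) and the other endocrine markers (adjusted p = 0.0107) passed the threshold. The other calls ended, with adjusted p of 0.0833 for diabetes loci, 0.262 for beta-cell transcription factors, 0.262 for stimulus-secretion coupling and 0.246 for exocytosis. The call at the other endocrine markers ended within 10 kb of gene ends (adjusted Fisher p = 0.0781) and among genes with H3K27ac at a gene end (adjusted Fisher p = 0.711), and that at exocytosis genes ended in both settings as well (0.0675 and 0.249). Among genes with H3K27ac at a gene end the call at stimulus-secretion coupling ended too (odds ratio 2.06, adjusted Fisher p = 0.214).

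**Figure D2:**
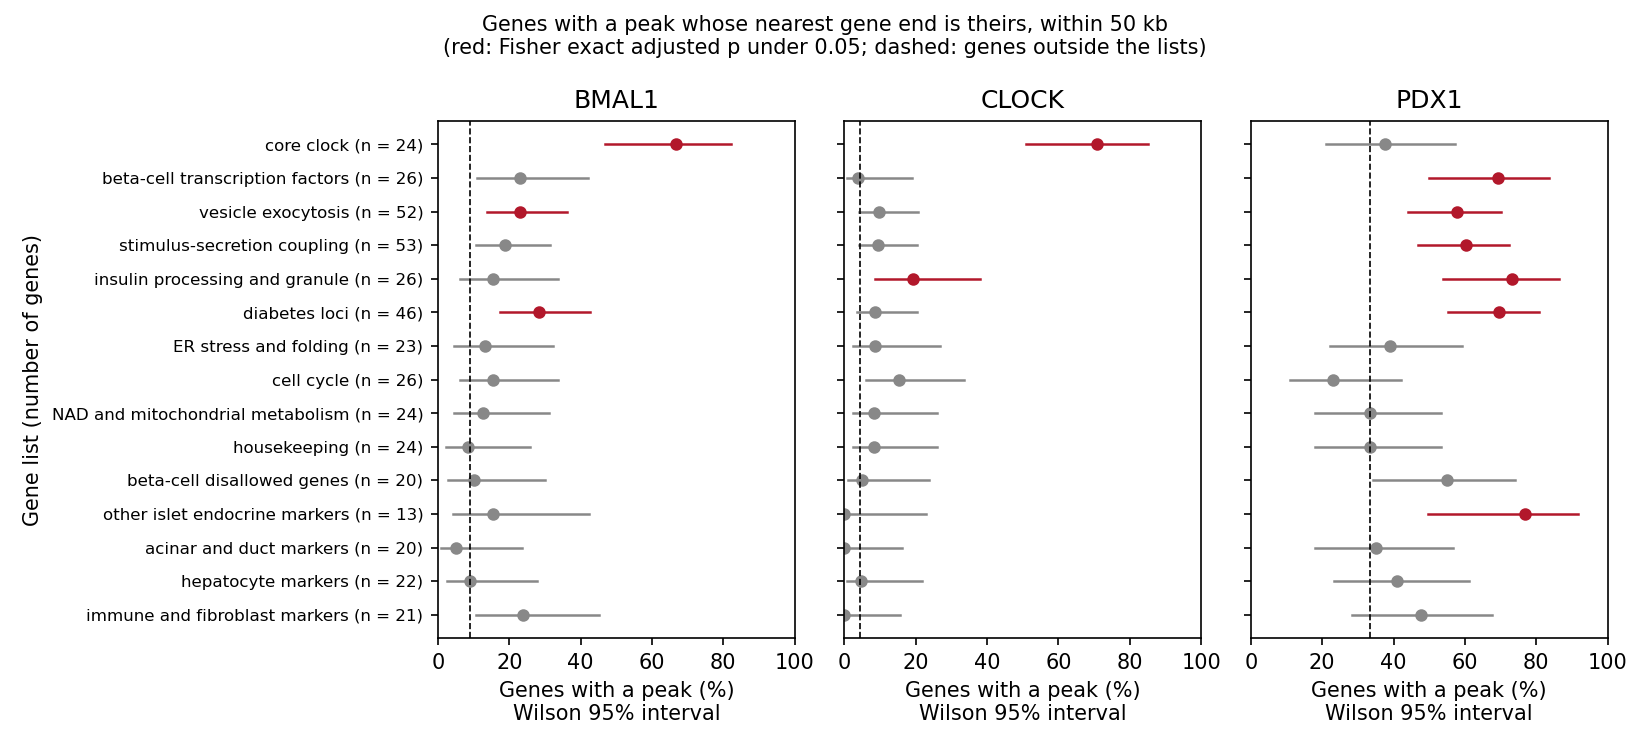
Share of the genes on each list (y axis, with the number of genes) that had a BMAL1, CLOCK or PDX1 peak within 50 kb of their ends (x axis, percent, lines are Wilson 95% intervals, the dashed line is the share among other genes, red marks an adjusted p under 0.05). Core clock genes stand at 66.7% for BMAL1 and 70.8% for CLOCK, and granule genes at 73.1% for PDX1.

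H3K27ac intervals were found at 48.7% of all protein-coding genes and at 25 of 26 insulin granule genes (96.2%, adjusted Fisher p = 2.85e-06), 46 of 53 stimulus-secretion genes (adjusted p = 1.55e-07), 45 of 52 exocytosis genes (adjusted p = 2.08e-07), 37 of 46 diabetes loci (adjusted p = 8.47e-05), 22 of 26 beta-cell transcription factor genes (adjusted p = 0.00101) and 18 of 24 core clock genes (adjusted p = 0.0349). The lists shared with most cell types were acetylated as well, at 22 of 23 ER stress genes (adjusted Fisher p = 1.57e-05), 22 of 26 cell cycle genes (adjusted p = 0.00101), 20 of 24 genes of NAD and mitochondrial metabolism (adjusted p = 0.00252) and 20 of 24 housekeeping genes (adjusted p = 0.00252). Some of these calls ended in other settings, the core clock list against territory-matched lists (adjusted permutation p = 0.115), diabetes loci within 10 kb of gene ends (adjusted Fisher p = 0.0531), and cell cycle (adjusted Fisher p = 0.296) and housekeeping genes (adjusted Fisher p = 0.347) with the upper 50% of every list by score. H3K27ac was less frequent at immune and fibroblast genes (4 of 21, odds ratio 0.248, adjusted Fisher p = 0.0216), a call that ended with the upper 50% of every list by score (adjusted Fisher p = 0.112). It was found at 5 of 20 acinar and duct genes (adjusted Fisher p = 0.0949, and 0.0438 within 10 kb of gene ends) and at 6 of 22 hepatocyte genes (adjusted p = 0.115). The 8 of 20 genes that beta cells are known to silence (adjusted Fisher p = 0.675) and 8 of 13 other endocrine markers (adjusted p = 0.605) did not differ past the threshold.

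With all peaks and genes within 50 kb, BMAL1 and CLOCK passed the threshold at none of the remaining lists. BMAL1 peaks were at 3 of 23 ER stress genes, 4 of 26 cell cycle genes, 3 of 24 NAD and mitochondrial genes, 2 of 24 housekeeping genes, 2 of 20 silenced genes, 2 of 13 other endocrine markers, 1 of 20 acinar and duct markers, 2 of 22 hepatocyte markers and 5 of 21 immune and fibroblast markers, with adjusted p from 0.0782 to 1. All 5 of those immune and fibroblast genes had a best BMAL1 score of 13 or 14. Their share of 23.8% and odds ratio of 3.20 were close to those of the vesicle exocytosis list (23.1% and 3.08), which holds more genes. CLOCK peaks were at 4 of 26 cell cycle genes (adjusted Fisher p = 0.0651), 2 of 23 ER stress genes, 2 of 24 NAD and mitochondrial genes, 2 of 24 housekeeping genes, 1 of 20 silenced genes, 1 of 22 hepatocyte markers, and 0 of the endocrine, acinar and immune markers. With CLOCK scores of 20 or more, a setting chosen after the data were seen, the cell cycle list passed (3 of 26 genes, odds ratio 9.28, adjusted Fisher p = 0.0185), and in the other settings its adjusted p ranged from 0.0794 to 0.414. PDX1 peaks were at 11 of 20 silenced genes (adjusted Fisher p = 0.115), 10 of 21 immune and fibroblast markers, 9 of 22 hepatocyte markers, 7 of 20 acinar and duct markers, 9 of 23 ER stress genes, 6 of 26 cell cycle genes, and 8 of 24 genes of each of the housekeeping and NAD lists, none past the threshold.

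Peak density differed between chromosomes. BMAL1 had 3.04 peaks per Mb on chromosome 4 and 2.99 on chromosome 5, against 0.181 on chromosome 9 and 0.176 on chromosome X. CLOCK ranged from 1.13 per Mb on chromosome 19 to 0.0410 on X, and PDX1 was densest on chromosome 14 and reached its lowest value, 4.46 per Mb, on X. Across the 20 chromosomes BMAL1 density followed the density of input tags, measured in H3K4me2 intervals, which ran from 6.14 tags per kb on X and 6.65 on chromosome 9 to 12.6 on chromosome 19 (Pearson r = 0.817, permutation p = 2e-05, adjusted 8e-05; Spearman rho = 0.729, permutation p = 0.00052, adjusted 0.00139, over 24 relations). Without chromosomes 9 and X, r was 0.719. The input in H3K4me2 intervals was the control of PDX1, H3K4me2 and H3K27ac. BMAL1 and CLOCK were called against the other input, which ran from 4.01 tags per kb on X to 5.93 on chromosome 19 in H2A.Z intervals. The relation of that other input to their peak densities was not tested. For CLOCK r was 0.925 and rho 0.883 (permutation p = 1e-05 for both, the smallest that 100000 permutations can give), and r was 0.897 without chromosomes 9 and X. For PDX1 r was 0.660 (permutation p = 0.00167) and rho 0.556 (permutation p = 0.0117), and without chromosomes 9 and X r fell to 0.392. On chromosomes above and below the median input density 17.8% and 20.4% of CLOCK peaks were in BMAL1, and 19.4% and 19.3% in PDX1. The shares of PDX1 peaks lay further apart, with intervals that did not overlap, at 0.963% and 0.558% in CLOCK, 0.750% and 0.458% in BMAL1, 3.68% and 2.54% in H2A.Z, and 22.4% and 24.9% in H3K4me2.

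**Figure D3:**
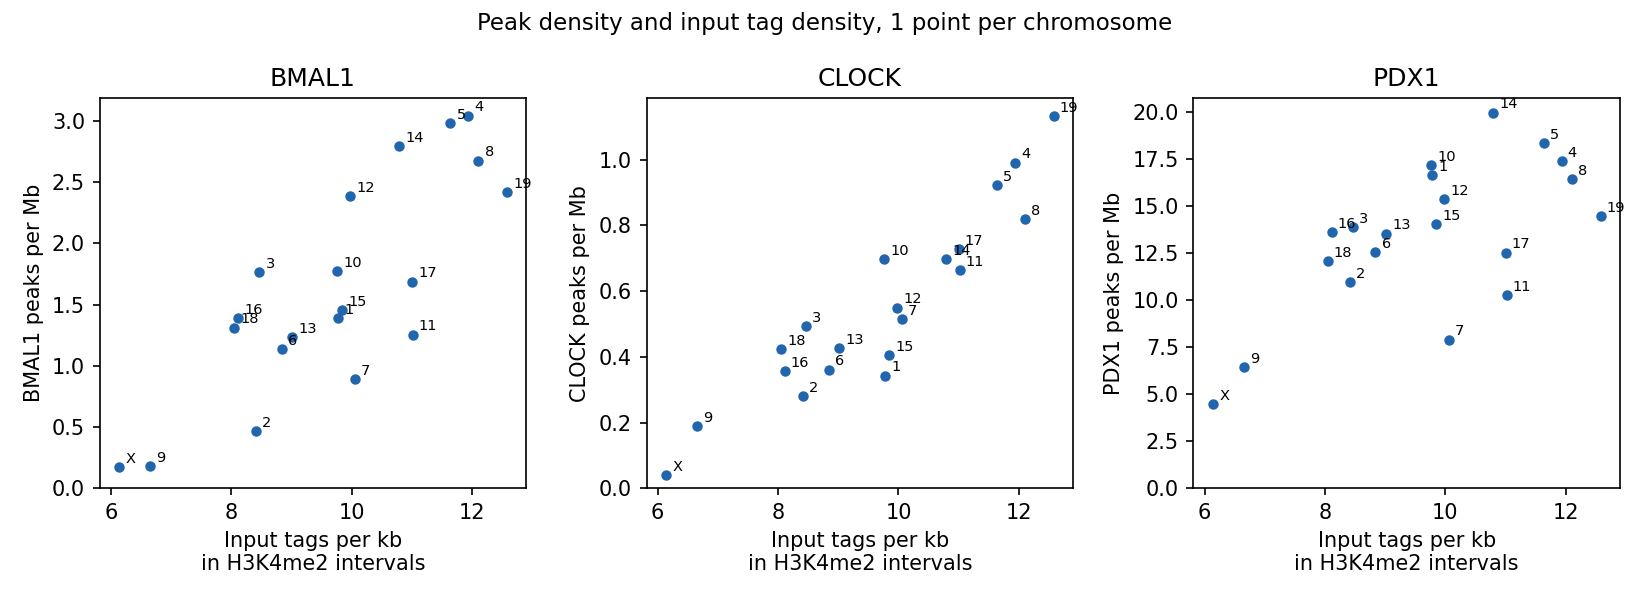
Peaks per Mb of BMAL1, CLOCK and PDX1 (y axis) against input tags per kb in H3K4me2 intervals (x axis), 1 labelled point per chromosome. Chromosomes X and 9 have the lowest input density, 6.14 and 6.65 tags per kb, and the lowest peak densities of all 3 factors. The input shown was the control of PDX1, and BMAL1 and CLOCK were called against the other input.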

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

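Peaks of at least 8 times the input, a planned filter that shortens every list, numbered 2445 for BMAL1, 748 for CLOCK, 8855 for H3K4me2, 11178 for H3K27ac and 9047 for H2A.Z. The tests with BMAL1 and CLOCK scores of 20 or more, and those within strata of width or chromosome, were chosen after the results were seen. The overlap of CLOCK with BMAL1, of both with PDX1 and with the 3 chromatin targets, and the shares at gene ends kept their direction and their side of the threshold under every alternative run for them. The enrichment of BMAL1 in enhancers with PDX1 did so as well, with odds ratios from 1.30 within tag-count quintiles of each chromosome to 1.87 at more than 5 kb from gene ends. For CLOCK the odds ratio stayed above 1 but missed the threshold with the upper 50% of every list (1.48, Fisher p = 0.0512) and with scores of 20 or more (1.49, Fisher p = 0.0506); both leave fewer occupied intervals, and the cause was not tested further. For BMAL1 the number of gene lists above background went from 3 to 1 within 10 kb of gene ends, to 1 among genes with H3K27ac at a gene end, to 1 against territory-matched lists and to 1 at scores of 20 or more. With the upper 50% of every list it stayed at 3, with beta-cell transcription factors (adjusted Fisher p = 0.0286) in the place of vesicle exocytosis (adjusted Fisher p = 0.334). For CLOCK it went from 2 to 1 within 10 kb, to 1 among acetylated genes and to 1 against matched lists. At scores of 20 or more it stayed at 2, with the cell cycle list (adjusted Fisher p = 0.0185) in the place of the granule list. For PDX1 it went from 6 to 4 within 10 kb, where other endocrine markers and exocytosis were lost, to 3 among acetylated genes and to 2 against matched lists. The core clock list passed for BMAL1 and CLOCK under all of these settings, and the cause of the other losses was not tested. For H3K27ac the 10 lists above and the 1 below became 0 and 0 among genes that have H3K27ac at a gene end, a background that fixes the outcome. The lists above became 9 within 10 kb (without diabetes loci), 9 against matched lists (without core clock) and 8 with the upper 50% of every list (without cell cycle and housekeeping), and the lists below background became 2 within 10 kb and 0 with the upper 50% of every list. Of 185 alternative values 127 kept direction and side of the threshold or, if counts, stayed within 1.5 times their number (as PDX1 peaks at 8 times the input did, 25187 of 34883), which for the list counts above did not always mean the same lists. A further 40 missed the threshold, and 18 were counts that moved. Of the 40, 1 turned direction, the granule list for CLOCK at scores of 20 or more. It had 0 of 26 genes against 1.40% of the other genes. Its odds ratio of 1.33 lay above 1 only through the correction for an empty cell. The rest of the 40 kept their direction. The CLOCK library placed 0.16% of its tags in peaks and the BMAL1 library 0.48%, and sites with fewer than 13 tags are not in these lists, so a missing overlap does not show that a factor was absent. The motif alternatives were not run. No paired analysis was possible because each target has 1 library and the labels give no replicate numbers shared between groups.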

Other observations

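The tests of input density, of gene content, of low-tag calls and of H3K27ac at all BMAL1 peaks outside CLOCK were chosen after the results were seen, and all genes in the next paragraph were chosen after their values were seen.

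Outside the clock and beta-cell lists, both clock factors had peaks at Ccne1, the cyclin E gene (best scores 35 for BMAL1 and 63 for CLOCK), and at Wee1, a kinase that delays entry into mitosis (17 and 23), and at both genes a BMAL1 peak overlapped CLOCK. The NAD salvage gene Nampt had scores of 16 and 21 without overlap of the peaks, and the housekeeping gene Ppia had 17 and 34 with overlap. Atf6, a sensor of endoplasmic reticulum stress, had a CLOCK peak on PDX1 (CLOCK score 20), as had Camk1d (21) and Creb1 (15) from the beta-cell lists. The 5 highest BMAL1 peaks outside CLOCK were nearest to Myf6 (136), Abcc8 (120), Tmc7 (102), Tmem229b (87) and Pde4b (82). Of these 5 peaks 1, that of Abcc8, was in H3K27ac, and 0 were in H3K4me2 or PDX1.

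Most BMAL1 peaks, 3867 of 4125, lay outside CLOCK peaks. The share on CLOCK was 75.5 percentage points higher at scores of 30 or more than at 13 or 14 (95% CI 67.8 to 83.2), which is consistent with many calls near the tag threshold that may be background. As a group they were not in the same kind of acetylated chromatin as the shared peaks, since H3K27ac overlap was 66.1 points lower outside CLOCK (61.1 to 71.1). This gap cannot decide whether some of them are BMAL1 sites without CLOCK in acetylated chromatin. CLOCK peaks were themselves in H3K27ac in 62.8% of cases, and background calls would lower the share outside CLOCK. Of the 3867 peaks outside CLOCK, 547 were in H3K27ac. At scores of 20 or more, where 113 of 139 peaks with CLOCK and 46 of 99 without were in H3K27ac, the gap was 34.8 points (23.1 to 46.6). Loss of weak CLOCK sites in a library with fewer tags in peaks stays open, and no biological explanation was tested, since no group of samples differs in the clock.

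PDX1 overlap was lower at the highest-scoring CLOCK peaks, 7.97% (11/138) against 21.9% (140/640) at scores of 15 to 29. A location of the strongest peaks at gene ends, where PDX1 is rare, does not account for it, since among peaks more than 1 kb from gene ends the odds ratio was 0.333 (95% CI 0.170 to 0.654). A candidate explanation is that part of the weaker CLOCK calls lie in strongly enriched PDX1 chromatin away from BMAL1. Within scores of 15 to 29, CLOCK peaks on PDX1 overlapped BMAL1 in 15 of 140 cases and the others in 114 of 500, an odds ratio of 0.406 (0.229 to 0.722), as that explanation needs. The strength of the PDX1 peaks did not enter this test, so it cannot tell that explanation from others. Among BMAL1 peaks the PDX1 share did not differ past the threshold between the same classes (5.17% and 6.75%, adjusted Fisher p = 0.778). The class of 15 to 29 was mixed, with 5.94% (64/1078) at 15 to 19 and 13.9% (17/122, 95% CI 8.89 to 21.2) at 20 to 29. From 20 to 29 to the highest class the BMAL1 share fell too, a step that was not tested. The lower PDX1 share at the strongest peaks thus cannot be called particular to CLOCK. Whether such calls reflect crosslinked open chromatin or recruitment of CLOCK by other proteins was not tested.

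The density of BMAL1 peaks differed between chromosomes, and for peaks with scores of 13 or 14 it did not follow genes per Mb (rho = -0.0887), while for scores of 20 or more a relation to gene content stays open (rho = 0.436, adjusted permutation p = 0.0885). At scores of 13 or 14 it followed input tag density (rho = 0.705), so that a difference in chromosome copy number in the line, acting on a fixed tag threshold, may contribute. The relation is not special to weak calls, since BMAL1 peaks with scores of 20 or more gave rho = 0.786 and the H3K4me2 intervals 0.777. Nor was it shared by the weak calls of every factor. PDX1 peaks, called at the same 13 tags, gave rho = 0.244 at scores of 13 or 14 (adjusted permutation p = 0.381) and 0.629 at 20 or more. For CLOCK the 2 values were 0.826 and 0.916. A fixed tag threshold alone therefore leaves the weak PDX1 calls unexplained. Input density was measured only inside called intervals, and base composition and mappability, which also move it, were not tested. No karyotype was used here, and no biological explanation was tested.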
